A study of Micropterus salmoides with 68 samples.

How the data were processed

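Liver and spleen RNA of largemouth bass was analysed from 68 libraries, 34 per tissue, in 9 groups per tissue with 3 or 4 libraries each. Per the labels' protocols, tissues were collected from single fish, RNA was extracted with TRIzol, ribosomal RNA was depleted and directional libraries were made with NEBNext kits. Per the submitters' processing notes, reads were trimmed with fastp 0.23.2 and quantified with Salmon 1.10.0. Genome build and annotation are not given in the sources. Deposited values are TPM per gene, per the labels, for 18666 genes in 68 columns, all used.

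The values were checked before any test. TPM sums lay between 995833.1 and 999253.8 per library, close to 1000000, with 2 decimals per value, and every gene reached 1 TPM in at least 3 libraries, so genes below that level are not in the table as deposited. No 2 libraries of a group were copies: over the 96 pairs within groups, at least 17643 genes differed and Pearson r of log2(TPM + 1) ran from 0.8006 to 0.9721. Of the gene names 18657 were found in a reference gene table for the species (assembly ASM1485139v1), used only for names and types. The other 9 are in date form and were left as they are. 17707 genes were protein-coding, 905 long noncoding, and 8139 carried only a locus number and were tested but not named. TPM keeps no record of depth, so depth per library is unknown and the counting error of low genes could not be given.

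Samples were grouped by the labels. Before the data were examined, the comparisons, tests, gene lists, rule for naming genes and most alternative settings were fixed. Each tissue had 1 fit with limma 3.58.1 in R 4.3.3 (group means of log2(TPM + 1), empirical Bayes with trend) over all 9 groups, with 25 residual and 4.8 (liver) or 4.89 (spleen) prior degrees of freedom. Genes with at least 1 TPM in at least 3 libraries of the tissue were tested, 15430 in liver and 17998 in spleen. Adjusted p is Benjamini-Hochberg within a comparison, with a threshold of 0.05. Comparisons were the end of transport and 1 day of recovery against before transport, fish labelled normal at 3, 4 and 5 days against before transport, and fish labelled abnormal against normal on each day and as the mean of the 3 days. A moderated F test asked whether that last difference changed with the day. Differences between tissues were tested as interactions in 1 fit of 18 groups and 18666 genes.

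Gene groups were 41 lists written before the data were examined, matched by gene symbol with paralogue suffixes. Those with at least 4 measured members, 39 in liver and 38 in spleen, were tested with limma's camera at its preset inter-gene correlation of 0.01, and again with an estimated correlation. Both were run for every comparison and are reported in full for 6, the first 2 and the mean of 3 days in each tissue. Counts of members "adjusted over the list alone" take Benjamini-Hochberg within the list.

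Genes were named by rule. In those 6 comparisons these were the 8 largest rises and the 8 largest falls past the threshold, with a gene symbol a mean of at least 5 TPM in the higher group and no overlap of the libraries of the 2 groups (for the mean of 3 days, the same direction on each day). Added to these were up to 3 members by smallest p of each of the 6 lists with the smallest camera p, and markers fixed in advance. In the other comparisons they were the 3 largest rises and 3 largest falls. This gave 161 genes and 269 gene-comparisons. Of the fixed markers, hspa1, hsp70, hamp, c3 and mx1 had no gene of that name, and il1b was not tested in liver. Genes outside the rule are named only where the text says that they were chosen after their values were seen.

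Alternatives fixed in advance were pseudocounts of 0.1 and 0.5, no filter, a filter of 5 TPM, median-of-ratios rescaling, quantile normalization, a fit of the compared groups alone, the replicate number as a block, array weights, robust empirical Bayes, an added threshold of 1 on the log2 difference, and leaving out each library in turn. Added after the data were seen were fits without libraries that stand apart, without the 10 most abundant genes of the tissue, and, at the end of transport in spleen and for the difference between tissues, without 487 genes at least 10 times higher in liver, and comparisons of fish labelled abnormal with fish before transport. Libraries were also regrouped in every other split, or in 100 splits where there were more. Tests for count data were not run because TPM are not counts. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 did the rest.

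The fits were tested on simulated data with 100 genes moved by a log2 difference of 1 and 100 moved by 2. At 1 and 2 they recovered 44% and 83% in liver at the end of transport, 27% and 82% after 1 day, and 26% and 82%, 35% and 84%, and 28% and 80% for fish labelled normal at 3, 4 and 5 days. Between labels in liver these were 17% and 75%, 32% and 87%, 28% and 76% by day, 85% and 99% for the mean, and 6% and 62% for the change with the day. In spleen they were 39% and 82% at the end of transport, 30% and 75% after 1 day, and 17% and 76%, 20% and 79%, and 24% and 79% for fish labelled normal. Between labels in spleen they were 14% and 70%, 27% and 88%, 12% and 80% by day, 78% and 95% for the mean, and 5% and 50% for the change with the day. For tissue differences they were 7% and 55% at the end of transport and 55% and 92% between labels. At most 11 unmoved genes were called in any comparison. A list moved by 1 was found by camera in all 6 comparisons with either correlation, and another list was called in 1 of them. Simulated genes varied independently, so false calls do not carry over to genes or lists that vary together (estimated correlation 0.744 for liver proteasome). Real groups differed in spread (r down to 0.8006 in spleen after 1 day), so rates may not hold for each.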

Results

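RNA sequencing measured gene expression in the liver and spleen of largemouth bass (Micropterus salmoides), a farmed freshwater fish, around a 4 h transport. Each tissue had 34 libraries from individually sampled fish in 9 groups: 4 fish taken right after netting from the pond, here called before transport, 4 at the end of transport, 4 after 1 day of recovery, and fish that the labels call normal or abnormal after 3, 4 and 5 days. There were 3 libraries of each kind at 3 days and 4 of each at 4 and 5 days. The labels do not define normal and abnormal, so both words stand here only for the labels. Fish were packed at 125 per box in 30 L of water and were not fed during the experiment. No fish kept without transport were analysed here, so time, fasting, tank and transport go together in every comparison with the fish before transport.

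Between 10814 and 14472 genes reached 1 TPM (transcripts per 1000000) in a liver library, and between 13320 and 16846 in a spleen library. Values are given as mean TPM ± SD, with n = 4 libraries per group unless stated, and as differences of log2(TPM + 1), which understate the change of low genes. Rankings of rises and falls cover only genes that meet the naming rule, which leaves out loci without a symbol. In liver, the first principal component (36.9% of the variance) placed all livers labelled normal on one side and all livers labelled abnormal on the other, the latter beside the livers taken before transport. In spleen the first component (32.9%) also parted the labels. The liver of fish 4 before transport lay apart from the other 3 of its group, as did the liver of fish 3 after 1 day.

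**Figure D1:**
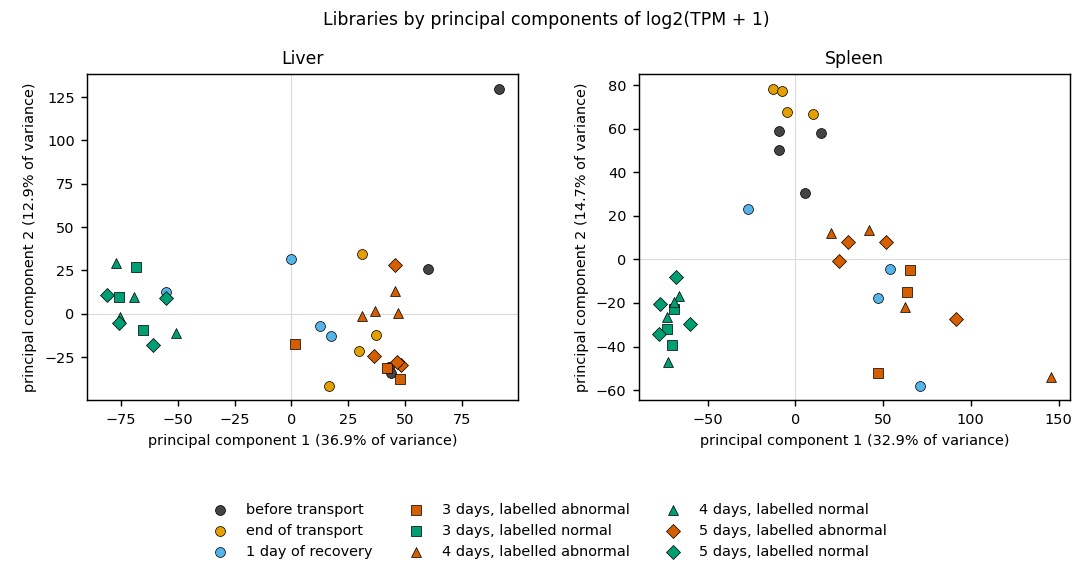
Scores of the 34 liver and 34 spleen libraries on the first and second principal components of log2(TPM + 1), with the percent of variance on each axis; each point is a library, coloured and shaped by group. Fish labelled normal at 3, 4 and 5 days form 1 cluster in each tissue, away from fish labelled abnormal.

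The first comparison asked what differed in liver between the end of transport and the time before it. Genes of the hypoxia response rose in liver: egln3, an oxygen-sensing prolyl hydroxylase, went from 7.31 ± 0.917 to 357 ± 211 TPM (log2 difference 5.23, SE 0.82, limma adjusted p = 0.000136). A sister enzyme, egln2, went from 9.80 ± 8.94 to 83.4 ± 17.7 (3.25), and epoa, which encodes the red-cell hormone erythropoietin, from 4.70 ± 2.08 to 50.1 ± 24.7 (3.12). Of the 22 measured members of the hypoxia list, 9 rose, none fell and 13 did not pass the test (12 rose when adjusted over the list alone). The list as a whole passed camera (adjusted p = 1.74e-14 with the preset correlation), but not with an estimated one (adjusted p = 0.248 with an estimated correlation).

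Some glycolysis and sterol genes also rose in liver. Of 15 glycolysis genes, 6 rose and 1 fell (6 and 2 when adjusted over the list alone; camera adjusted p = 7.59e-07, adjusted p = 0.432 with an estimated correlation). Among them pgam1b, a phosphoglycerate mutase, rose from 11.1 ± 2.11 to 118 ± 40.5 TPM (3.25), ldha, which makes lactate from pyruvate, from 17.2 ± 9.48 to 109 ± 60.3 (2.57), and pfkpa, a phosphofructokinase, from 2.96 ± 1.5 to 13.6 ± 4.22 (1.91). In the cholesterol synthesis list 2 of 22 genes rose (3 when adjusted over the list alone, camera adjusted p = 1.61e-07, adjusted p = 0.923 with an estimated correlation). These were the sterol reductase gene tm7sf2 (3.40 ± 2.38 to 61.7 ± 41.5, 3.71) and insig1, a brake on sterol synthesis (61.3 ± 57.5 to 291 ± 129, 2.57). Other large rises were upp1, a uridine phosphorylase (8.10 ± 1.79 to 217 ± 81.2, 4.5), g0s2, an inhibitor of triglyceride lipase (81.1 ± 14.4 to 1249 ± 296, 3.91), znf395a (4.37) and tmem45a (3.84).

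Falls in liver at the end of transport included genes of the circadian clock: nr1d2a, a clock repressor, went from 120 ± 87.3 to 14.3 ± 2.89 TPM (-2.78) and ciarta, another clock repressor, from 8.07 ± 4.36 to 0.475 ± 0.325 (-2.53). In the clock list 10 of 23 genes fell and 2 rose (10 and 3 when adjusted over the list alone), and the list did not pass camera (adjusted p = 0.0629, adjusted p = 0.923 with an estimated correlation), but passed after median-of-ratios rescaling (0.0373) and with a pseudocount of 0.1 (0.0344). Other large falls were gch2, a GTP cyclohydrolase (39.8 ± 2.85 to 3.21 ± 2.99, -3.65), and mych of the Myc family (76.4 ± 48.1 to 8.85 ± 1.42, -2.75). Falls of plch2a (-2.65), arhgef28a (-2.60), map3k5 (-2.55) and ncor1 (-2.46) set low end-of-transport values against widely spread values before transport. Of the stress markers fixed in advance, the growth-factor binding protein gene igfbp1a went from 102 ± 67.8 to 631 ± 260 TPM without passing (2.88, adjusted p = 0.0617; 0.0248 after median-of-ratios rescaling). The chaperone gene hspa5 (-0.44, adjusted p = 0.76), fkbp5 of glucocorticoid signalling (0.90, 0.379) and pck1 of gluconeogenesis (2.44, 0.162) did not pass either.

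3 further lists in liver passed camera at the end of transport with few or no single genes behind them. Cytosolic ribosomal proteins had 0 of 63 genes past the threshold (0 when adjusted over the list alone; median log2 difference 0.35, adjusted p = 4.79e-16) and the proteasome 0 of 29 (0 over the list alone; median 0.19, adjusted p = 0.000576). In oxidative phosphorylation 4 of 33 rose (4 rose and 1 fell when adjusted over the list alone, camera adjusted p = 6.61e-09). Examples are ndufa4b (48.6 ± 22.7 to 165 ± 35.9, 1.85), ndufs4 (35.1 ± 9.40 to 67.6 ± 10.1, 0.95) and sdha (42.5 ± 23.0 to 63.5 ± 4.42, 0.69). With an estimated correlation the adjusted p was 0.923 for each of these 3 lists. Median-of-ratios rescaling also brought past the threshold cell cycle (4 of 22 fell, 1 rose; 0.0373, 0.0861 as deposited) and oxidative stress (2 of 29 rose, 1 fell; 0.0373, 0.097 as deposited). The call of sdha was lost without 6 of the 8 libraries in turn, and that of ndufa4b without fish 4 before transport.

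In all, limma called 1886 of 15430 genes in liver at the end of transport, 456 higher and 1430 lower. The median log2 difference of all genes was -0.27, and after median-of-ratios rescaling 2745 genes were called, 1372 higher and 1373 lower. The count moved by over 1.5 times without fish 1 (3588), 2 (3220) or 4 (1123, of them 581 higher and 542 lower) before transport, or fish 2 (830) or 4 (855) at its end. With only the 8 compared libraries in the fit 139 genes were called, and plch2a, arhgef28a, map3k5, ncor1, ndufs4, sdha and insig1 were not among them.

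After 1 day of recovery proteasome and cholesterol synthesis genes, and some genes of the unfolded protein response, were higher in liver. Proteasome genes rose in 20 of 29 cases with none lower (21 when adjusted over the list alone; camera adjusted p = 4.90e-13, adjusted p = 0.91 with an estimated correlation). Examples are psmd7 (6.72 ± 1.69 to 23.2 ± 11.6 TPM, 1.56), psmd11b (1.85) and psmc5 (11.3 ± 1.19 to 36.5 ± 10.7, 1.58). Cholesterol synthesis had 14 of 22 higher (16 when adjusted over the list alone, camera adjusted p = 2.71e-09, adjusted p = 0.91 with an estimated correlation). Examples are fdps, which makes farnesyl diphosphate (3.23 ± 1.86 to 77.6 ± 49.1, 4.15), tm7sf2 (3.40 ± 2.38 to 78.4 ± 42.1, 4.15) and nsdhl (4.80 ± 4.77 to 43.4 ± 20.8, 3.16). Genes of the unfolded protein response of the endoplasmic reticulum rose in 9 of 26 cases (17 rose and 1 fell when adjusted over the list alone, camera adjusted p = 1.19e-06, adjusted p = 0.91 with an estimated correlation). They included creld2 (4.54 ± 2.46 to 47.6 ± 37.4, 2.96), dnajb11 (2.75), manf (2.80) and the chaperone gene hspa5 (66.7 ± 56.6 to 664 ± 800, 2.94, adjusted p = 0.0141; 0.0946 without fish 3 after 1 day).

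Of 19 glucocorticoid-responsive genes in liver after 1 day, 10 fell and none rose (12 when adjusted over the list alone, camera adjusted p = 0.000467, adjusted p = 0.91 with an estimated correlation). Among them errfi1a, an inhibitor of the epidermal growth factor receptor, went from 74.6 ± 37.3 to 7.39 ± 4.65 TPM (-3.25), tsc22d3, the glucocorticoid-induced leucine zipper, from 215 ± 63.4 to 64.9 ± 42.0 (-1.90), and nr3c2, the mineralocorticoid receptor, from 7.45 ± 8.62 to 0.960 ± 0.610 (-1.70). Cell cycle genes fell in 8 of 22 cases (9 when adjusted over the list alone, camera adjusted p = 0.0014, adjusted p = 0.91 with an estimated correlation). Among these were ccna2 (-1.55), cdc20 (-1.55) and ccnb2 (-1.19), all under 5 TPM before transport. Ribosome biogenesis had 10 of 29 higher and 1 lower (12 and 2 when adjusted over the list alone, camera adjusted p = 0.000355, adjusted p = 0.91 with an estimated correlation). Among these were rrp12 (2.07) and rrp9 (1.43) higher and npm1b (-1.76) lower.

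Outside these groups, large rises in liver after 1 day were c7b, a terminal complement component (141 ± 109 to 3116 ± 1666, 4.59), and odc1, the entry enzyme of polyamine synthesis (1.56 ± 0.722 to 54.6 ± 57.2, 3.84). Others were the translation factor gene eif4e1c (3.94), the gelatinase gene mmp9 (0.760 ± 0.623 to 25 ± 13.5, 3.81), tbl2 (3.70) and pla2g3 (3.68). Large falls were adrb2a, a beta-adrenergic receptor (108 ± 111 to 7.96 ± 5.58, -3.51), arrdc3a (-3.47) and ddit4, an inhibitor of TOR signalling (193 ± 163 to 14.8 ± 4.52, -3.27). So were gadd45ga (-3.16), slc25a36a (-3.05), dmgdh of choline breakdown (199 ± 132 to 28.8 ± 15.8, -2.75) and fam13a (-2.69). The markers fkbp5 (1.13, adjusted p = 0.221), pck1 (-0.52, 0.78) and igfbp1a (-2.21, 0.106) did not pass.

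6 more lists passed camera in liver after 1 day. Endothelial and stromal markers fell in 10 of 25 cases (13 when adjusted over the list alone, camera adjusted p = 0.00206), immediate early genes in 6 of 15 with 1 higher (7 and 1 over the list alone; 0.0196) and amino acid catabolism in 13 of 28 with 3 higher (14 and 3 over the list alone; 0.0233). The growth axis fell in 5 of 13 (7 over the list alone; 0.0435) and the clock in 9 of 23 with 2 higher (9 and 2 over the list alone; 0.0492). Cytosolic ribosomal proteins had 1 of 63 higher (0 over the list alone; 0.0134). With an estimated correlation the adjusted p was 0.941 for the clock and the ribosomal proteins and 0.91 for the other 4, and after median-of-ratios rescaling amino acid catabolism (0.127), the growth axis (0.0555) and the clock (0.0745) no longer passed.

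In liver after 1 day 4218 of 15430 genes were called, 1542 higher and 2676 lower. The median of all genes was -0.16, and median-of-ratios rescaling gave 2732 higher and 2825 lower. Without fish 3 after 1 day 1941 genes were called, and without that fish and fish 4 before transport 2091, of which 1345 were higher and 746 lower. With only the 8 compared libraries in the fit the count was 194, and the calls of fam13a, psmd7, psmd11b, dnajb11, manf, npm1b, rrp9, tsc22d3, nr3c2, ccna2, cdc20, ccnb2 and hspa5 ended.

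In spleen at the end of transport hypoxia and glycolysis genes rose, as in liver, and so did transcripts typical of hepatocytes. Of the other 4 lists that passed in liver, cholesterol synthesis (camera adjusted p = 0.371), oxidative phosphorylation (0.488) and cytosolic ribosomal proteins (0.414) did not pass in spleen, and the proteasome moved the other way. Hypoxia genes rose in 13 of 23 cases with none lower (15 when adjusted over the list alone; camera adjusted p = 2.61e-16, adjusted p = 0.13 with an estimated correlation). Examples are egln3 (8.35 ± 2.97 to 191 ± 99.6 TPM, log2 difference 4.29, SE 0.66, adjusted p = 8.19e-05), the collagen prolyl hydroxylase gene p4ha1b (14.1 ± 2.74 to 268 ± 70.5, 4.14) and egln2 (11.9 ± 3.51 to 146 ± 42.2, 3.5). Also higher were pfkfb4b (18.8 ± 4.96 to 100.4 ± 17.6, 2.37) and igfbp1a (1.79 ± 0.921 to 35.4 ± 18.7, 3.62, adjusted p = 0.000555). Glycolysis rose in 11 of 16 cases with 1 lower (11 and 1 when adjusted over the list alone, camera adjusted p = 3.40e-13, adjusted p = 0.088 with an estimated correlation). Among these were ldha at 132 ± 33.3 before and 1242 ± 321 after (3.21), the enolase gene eno1a at 136 ± 25.6 and 1112 ± 203 (3.02) and tpi1b at 112 ± 25.7 and 668 ± 122 (2.57).

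**Figure D2:**
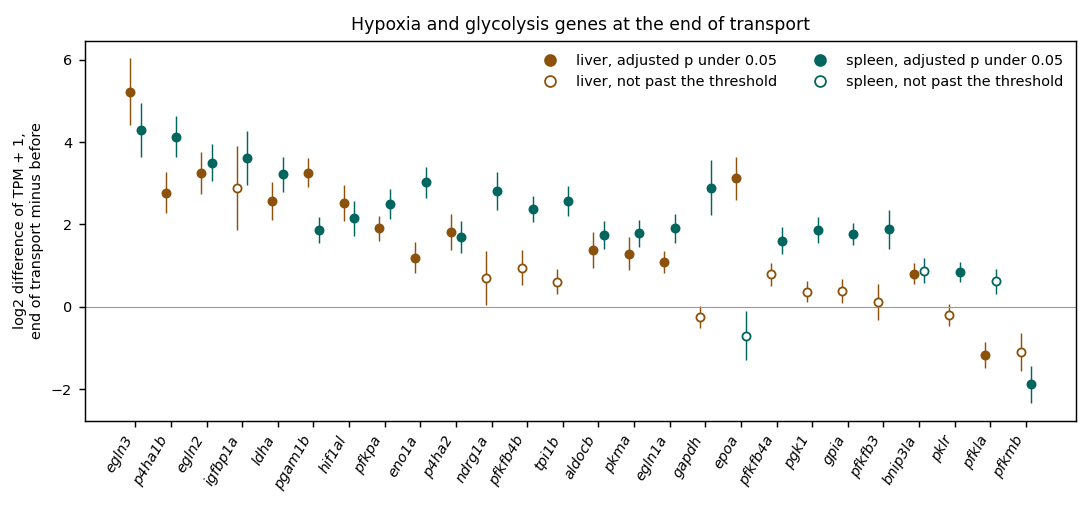
Log2 differences of TPM + 1 at the end of transport against before for the hypoxia and glycolysis genes past the threshold in at least 1 tissue; points are fitted differences, bars their standard errors, and open points did not pass. Of the genes shown, egln3 had log2 differences of 5.23 in liver and 4.29 in spleen, and epoa 3.12 in liver and -0.70 in spleen.

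Transcripts typical of liver also rose in spleen at the end of transport. Hepatocyte markers rose in 17 of 22 cases (20 when adjusted over the list alone, camera adjusted p = 1.61e-16, adjusted p = 0.213 with an estimated correlation). Examples are tdo2a of tryptophan breakdown (0.943 ± 0.451 to 14.1 ± 9.53 TPM, 2.70), vtnb (2.51) and tat (2.19). The summed TPM of the hepatocyte markers was 561 ± 180 before transport and 4291 ± 2643 at its end. Coagulation genes rose in 12 of 19 cases (13 when adjusted over the list alone, camera adjusted p = 7.16e-09, adjusted p = 0.255 with an estimated correlation). Examples are kng1 (3.5), f2 (3.23) and f9b (1.40). Acute phase genes rose in 6 of 10 cases (6 rose and 1 fell when adjusted over the list alone, camera adjusted p = 1.36e-06, adjusted p = 0.255 with an estimated correlation). Among these were the haem scavenger gene hpxa (8.90 ± 3.67 to 259 ± 205, 4.36), fetub (3.78) and itih2 (2.56), and ahsg2 (6.25 ± 2.19 to 179 ± 134, 4.24) rose beside them. Hepatocytes are the usual source of these secreted proteins.

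Rises outside these groups in spleen were znf395a (3.39 ± 0.098 to 217 ± 86.6, 5.56), mmp9 (7.58 ± 3.36 to 262 ± 150, 4.83), the stress-inducible nuclear protein gene nupr1b (28.9 ± 19.8 to 523 ± 148, 4.34) and myoglobin, mb (0.378 ± 0.452 to 24.5 ± 4.34, 4.25). Proteasome genes fell in 15 of 29 cases (20 when adjusted over the list alone, camera adjusted p = 2.78e-09, adjusted p = 0.496 with an estimated correlation). Examples are psmc5 (59.0 ± 7.91 to 24.0 ± 3.97, -1.27), psmc6 (-1.15) and psma5 (-1.12). The largest single falls were the small GTPase gene rrad (467 ± 117 to 32.2 ± 22.8, -4.13), brinp3a.1 (-2.88), the growth factor gene gdf11 (-2.81) and ciarta (14.6 ± 2.01 to 1.30 ± 0.126, -2.76). Others were the cadherin gene cdh11 (-2.63), ccbe1 of lymphatic growth (59.7 ± 2.90 to 9.47 ± 0.888, -2.54), fgf12a (-2.5) and gfra1b (-2.45). The markers hspa5 (-0.97, adjusted p = 0.209; 0.00441 with only the 8 compared libraries in the fit), fkbp5 (-0.46, 0.78) and pck1 (0.32, 0.467) did not pass.

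10 further lists passed in spleen at the end of transport. Higher on the whole were the glucocorticoid response (5 of 19 rose, 1 fell, 6 and 1 over the list alone, camera adjusted p = 0.00152), complement (3 of 11, 5 over the list alone; 0.0029), neutrophil markers (2 of 7, 4 over the list alone; 0.00581), autophagy (2 of 26, 2 over the list alone; 0.0181), haem and iron (3 of 11 with 1 lower, 3 and 1 over the list alone; 0.0181) and amino acid catabolism (6 of 27, 6 and 2 lower over the list alone; 0.0497). Lower were immediate early genes (7 of 20, 9 and 1 higher over the list alone; 0.00281), the unfolded protein response (3 of 26, 4 over the list alone; 0.0054), ribosome biogenesis (4 of 29 with 1 higher, 5 and 1 over the list alone; 0.00581) and cytosolic heat shock (3 of 19, 4 over the list alone; 0.0416). Adjusted p with an estimated correlation was 0.496 for the glucocorticoid, complement, neutrophil and haem lists, 0.826 for immediate early genes and 0.862 for the other 5. After median-of-ratios rescaling the neutrophil (0.0527), haem (0.0663) and amino acid (0.168) lists no longer passed, nor did the last with a pseudocount of 0.1 (0.0608).

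The spleen total at the end of transport was 2197 of 17998 genes, 941 higher and 1256 lower, and 1924 (709 higher, 1215 lower) without 487 genes that are at least 10 times higher in liver. Rescaling raised it to 4709 with median of ratios and 4832 with quantiles, the 8 compared libraries alone gave 6177, array weights 7405 and taking out the 10 most abundant genes 3506. Leaving out fish 2 at the end of transport gave 1422.

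After 1 day of recovery red-cell genes were higher in spleen and ribosomal protein genes lower, and a few abundant transcripts took more of the TPM. Erythroid markers rose in 15 of 17 cases (15 when adjusted over the list alone; camera adjusted p = 6.86e-21, adjusted p = 0.124 with an estimated correlation). Examples are the spectrin gene sptb of the red-cell membrane (9.58 ± 2.60 to 309 ± 431 TPM, 3.85), the mitochondrial iron carrier gene slc25a37 (20.9 ± 8.99 to 156 ± 150, 2.52) and the transferrin receptor gene tfr1a (24.7 ± 4.99 to 148 ± 114, 2.29). Ankyrin, ank1a, rose with them (5.36 ± 0.817 to 126 ± 177, 3.33). Fish 4 lay apart in the summed TPM of erythroid markers, at 11797 against 2233 to 2825 in the other 3, and raises these means. Without it the 4 genes still passed, with smaller log2 differences. Cytosolic ribosomal protein genes fell in 59 of 63 cases (59 when adjusted over the list alone, camera adjusted p = 1.09e-22, adjusted p = 0.894 with an estimated correlation). Examples are rpl37 (-2.14) and rps15 (-2.17). The 10 genes most abundant in spleen took 15.6 ± 4.5% of the TPM before transport and 39.8 ± 9.7% after 1 day. In 1 of the 4 spleens the ribosomal protein gene rps3a alone stood at 274347 TPM, against 954 to 2060 in the other 3.

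Immediate early genes fell in spleen in 12 of 20 cases (12 when adjusted over the list alone, camera adjusted p = 1.48e-05, adjusted p = 0.953 with an estimated correlation). Among these were nr4a1 (23.4 ± 4.32 to 2.22 ± 1.95, -3.06), jund (118 ± 43.8 to 17.9 ± 5.64, -2.64) and fosb (-1.95). Neutrophil markers rose in 3 of 7 cases (3 when adjusted over the list alone, camera adjusted p = 0.000768, adjusted p = 0.751 with an estimated correlation): mmp9 went from 7.58 ± 3.36 to 798 ± 428 (6.48), nccrp1 from 35 ± 9.04 to 264 ± 165 (2.71), and ncf1 of the phagocyte oxidase from 28.6 ± 9.02 to 68.8 ± 31.7 (1.19, adjusted p = 0.0407). Oxidative phosphorylation fell in 16 of 33 cases (23 when adjusted over the list alone, camera adjusted p = 0.000189, adjusted p = 0.991 with an estimated correlation). Examples are ndufa4a (-2.05), ndufa2 (-1.66) and sdhc (-1.63). Ribosome biogenesis rose in 4 of 29 (4 over the list alone, camera adjusted p = 0.000266, adjusted p = 0.991 with an estimated correlation). Examples are utp20 (1.54), rrp12 (1.33) and nop2 (1.06).

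Single genes that fell most in spleen after 1 day were rrad (467 ± 117 to 4.75 ± 1.95, -6.38), ddit4 (611 ± 215 to 37.4 ± 22.9, -4.21) and atp5l of the ATP synthase (-4.16). They were followed by mafk (-3.51), the transcription factor gene cebpd (465 ± 45.7 to 49.5 ± 22.1, -3.34), cunh11orf96 (-3.15) and the chemokine receptor gene ccr9a (445 ± 78.0 to 52.5 ± 8.81, -3.06). Rises included ahnak (3.42), the phosphate carrier gene slc20a1a (17.0 ± 6.88 to 174 ± 131, 3.12), atp8b4 (3.11), the metalloreductase gene steap4 (1.28 ± 0.802 to 29.7 ± 35.6, 3.01, adjusted p = 0.0223) and cebp1 (3.00). The markers hspa5 (-0.11, adjusted p = 0.903), fkbp5 (-1.10, 0.323), pck1 (-0.17, 0.685) and igfbp1a (-0.91, 0.346) did not pass. 5 other lists passed camera: oxidative stress (7 of 30 rose, 1 fell, 10 and 3 over the list alone; 0.00317), the proteasome (0 of 29, 0 over the list alone, median 0.20; 0.00583), thrombocyte markers (2 of 11 rose, 4 over the list alone; 0.0182), coagulation (2 of 19 rose, 1 fell, 3 and 1 over the list alone; 0.0392) and, lower, the glucocorticoid response (5 of 19 fell, 1 rose, 9 and 1 over the list alone; 0.0446). All 5 had an adjusted p of 0.991 with an estimated correlation, and thrombocyte (0.0524), coagulation (0.281) and glucocorticoid (0.0534) lists did not pass after median-of-ratios rescaling. Cell cycle (6 of 33 fell; 0.0296 rescaled, 0.0405 with a pseudocount of 0.1, 0.0599 as deposited) and endothelial and stromal markers (9 of 26 fell, 1 rose; 0.0472, 0.0765 as deposited) then did.

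Counts for spleen after 1 day depended strongly on scaling and on 2 fish. As deposited 3609 of 17998 genes were called, 750 higher and 2859 lower, with a median of all genes of -0.23. Median-of-ratios rescaling gave 6182 (2938 higher, 3244 lower), quantile normalization 6166, array weights 8946, and taking out the 10 most abundant genes 5158 (3638 higher, 1520 lower). The count was 2369 without fish 1 before transport, 1838 without fish 3 after 1 day, 6454 without fish 4 after 1 day and 2557 without the last 2, where ahnak, steap4, atp5l, ndufa4a, ndufa2, sdhc, utp20, rrp12, nop2 and ncf1 no longer passed. Without fish 3 and 4 after 1 day the log2 difference was -0.753 for atp5l, 0.615 for ahnak and -0.766 for ndufa4a, so their sizes rest largely on these fish. Leaving out 5 of the 8 libraries, 1 at a time, ended the call of ncf1. With only the 8 compared libraries in the fit 504 genes were called and rpl37 and rps15 were not among them.

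Between the labels, the largest rises among genes with a symbol in livers labelled abnormal over livers labelled normal were fabp10a, hpxa and rnasel2. The livers labelled normal lay further from the livers before transport. In every liver labelled normal the most abundant gene was an unnamed locus, LOC119897996 or LOC119897998, singled out after their values were seen. Neither was the most abundant gene of a liver labelled abnormal. Averaged over 3, 4 and 5 days (n = 11 livers per label), hpxa, which encodes the haem scavenger hemopexin, stood at 7489.8 ± 2637 TPM in fish labelled abnormal and 65.9 ± 76.8 in fish labelled normal (log2 difference 7.54, SE 0.38, limma adjusted p = 9.85e-16), against 14165 before transport. The ribonuclease-like gene rnasel2 stood at 1146 ± 334 and 14.0 ± 6.60 (6.30) and igfals, which holds insulin-like growth factors in the blood, at 309.9 ± 51.3 and 18.4 ± 11.5 (4.18). In the livers labelled normal the bile-acid and fatty-acid carrier gene fabp10a was listed at 0 in all 7 libraries of 3 and 4 days and in 3 of 4 at 5 days, where the other had 72.2 TPM. In livers labelled abnormal its mean was 348 ± 173 TPM. Also higher in livers labelled abnormal were acsf2 (4.69), rdh1 (4.49), pipox of sarcosine breakdown (4.23) and tfr1a (175 ± 56.8 against 9.84 ± 6.48, 4.10).

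Lower in livers labelled abnormal, and so higher in livers labelled normal, were the hyaluronan receptor gene layna (1.21 ± 2.76 against 80.5 ± 38.2 TPM, -5.34), the transglutaminase gene tgm2l (-5.22), upp1 (12.0 ± 7.94 against 347 ± 140, -4.85), odc1 (2.37 ± 1.75 against 86.6 ± 37.4, -4.73), the magnesium transporter gene slc41a1 (-4.48), the aquaporin gene aqp12 (-4.04) and pck1 (4.08 ± 5.37 against 92.3 ± 98.0, -4.01). Serum amyloid A, saa, a major acute-phase protein, stood at 3177 ± 5989 TPM in livers labelled abnormal and 20328 ± 9781 in livers labelled normal (-3.98, adjusted p = 0.00153). Of the 9 acute phase genes measured 3 rose and 6 fell (3 and 6 over the list alone), and the list did not pass camera (adjusted p = 0.21, adjusted p = 0.867 with an estimated correlation). Nor did the glucocorticoid response (5 rose and 10 fell of 19, camera adjusted p = 0.147) and cytosolic heat shock (6 rose and 7 fell of 19; 0.908).

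**Figure D3:**
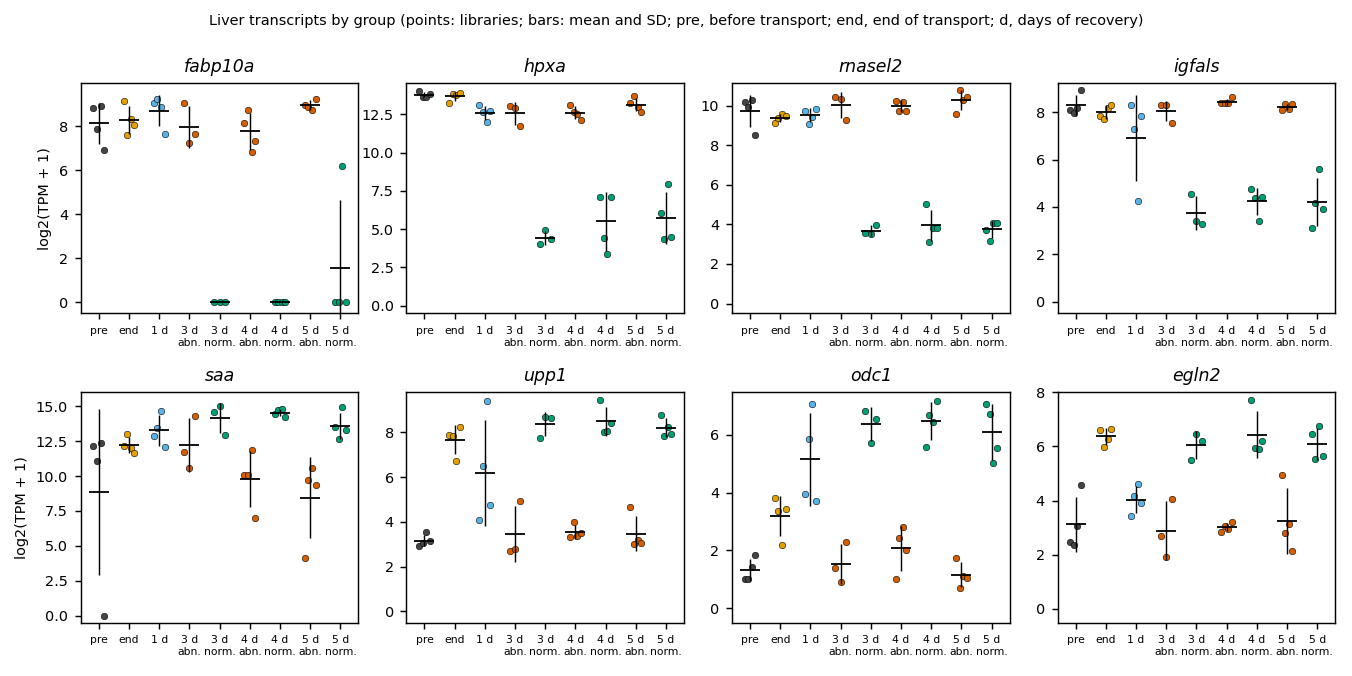
Log2(TPM + 1) of 8 genes in the 34 livers by group; points are libraries, bars the group mean and SD, and the labels at 3, 4 and 5 days stand for fish labelled abnormal (abn.) or normal (norm.). In livers labelled normal fabp10a, hpxa, rnasel2 and igfals lie below, and upp1, odc1 and egln2 above, the values before transport.

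Lists of liver genes also differed between the labels. Proteasome genes were lower in livers labelled abnormal in 27 of 29 cases and higher in 1 (27 and 1 when adjusted over the list alone; camera adjusted p = 2.24e-10, adjusted p = 0.867 with an estimated correlation). Examples are psmd2 (-1.68), psmc4 (-1.79) and psmd12 (-1.56). Hypoxia genes were lower in 13 of 22 and higher in 1 (14 and 2 over the list alone, camera adjusted p = 0.000543). Among these were egln2 (9.07 ± 7.69 against 81.0 ± 46.6, -3.14), epoa (1.64 ± 1.44 against 25.2 ± 22.8, -2.99) and ddit4 (41.3 ± 32.6 against 445 ± 283, -3.56). The unfolded protein response was lower in 16 of 26 and higher in 2 (16 and 2 over the list alone, camera adjusted p = 0.00406). Among these were creld2 (9.78 ± 6.65 against 97.6 ± 61.0, -3.16), atf4b (-1.64) and dnajc3a (-1.54). Cell cycle genes were lower in 9 of 22 and higher in 2 (9 and 2 over the list alone, camera adjusted p = 0.027). With an estimated correlation the adjusted p of these 3 lists was 0.867 as well.

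Higher in livers labelled abnormal were fatty acid oxidation genes in 12 of 26 cases (12 over the list alone, camera adjusted p = 0.00997). Among these were acadl (129.8 ± 15.1 against 51.2 ± 11.3 TPM, 1.35), etfb (1.23) and hadh (131 ± 29.7 against 35.9 ± 12.6, 1.88). Erythroid markers were higher in 13 of 17 and lower in 1 (13 and 1 over the list alone; 0.0161). Among these were the red-cell carbonic anhydrase gene cahz (19.6 ± 10.9 against 2.81 ± 1.41, 2.33) and hemgn (1.61). The clock was higher in 17 of 23 and lower in 3 (17 and 3 over the list alone; 0.0161). Among these were rorc (2.13) and nr1d2b (1.72) higher and nfil3-2 (-1.75) lower. Hepatocyte markers were higher in 14 of 24 and lower in 6 (15 and 6 over the list alone; 0.0279), and coagulation genes higher in 12 of 20 and lower in 4 (12 and 5; 0.038). Interferon genes were higher in 15 of 21 and lower in 2 (15 and 3; 0.0395), amino acid catabolism higher in 14 of 28 and lower in 8 (14 and 8; 0.0485), T cell markers higher in 6 of 9 (6; 0.027) and pancreas markers in 4 of 5 (4; 0.027). With an estimated correlation the adjusted p of each of these 9 lists was 0.867. After median-of-ratios rescaling 7 of the 13 lists that passed still did, and fatty acid oxidation (0.0509), hepatocyte (0.0955), coagulation (0.0923), amino acid (0.131), pancreas (0.0627) and cell cycle (0.0627) lists did not. Amino acid catabolism did not pass with a pseudocount of 0.1 either (0.0643). Because erythroid, T cell and pancreas markers moved with the label, a share of other cells that differs between the livers goes with each of these groups.

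Over the 3 days together 7772 of 15430 liver genes were called, 4485 higher and 3287 lower in fish labelled abnormal, of which 2719 had a log2 difference of at least 1. By day there were 2731 at 3 days (1180 higher, 1551 lower), 4028 at 4 days (2729 and 1299) and 4447 at 5 days (2795 and 1652). The median of all genes was 0.19 at 4 days and 0.16 at 5 days, and median-of-ratios rescaling gave 2543 higher and 2715 lower at 4 days and 3078 and 3139 at 5 days. Other settings, given below, moved these counts. Leaving out a fish labelled abnormal at 3 days gave 1562 (fish 1) or 1390 (fish 2) genes, and a fish labelled normal 1814 (fish 1) or 1657 (fish 3).

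On each day hpxa, fabp10a and rnasel2 were the 3 largest rises among genes with a symbol in livers labelled abnormal. Hemopexin, hpxa, differed by 8.13, 7.10 and 7.4 at 3, 4 and 5 days, rnasel2 by 6.36, 6.03 and 6.52, and fabp10a stood at 288 ± 203 (n = 3), 244 ± 138 and 497 ± 79.3 TPM in livers labelled abnormal. The largest falls were tgm2l (-5.57 at 3 days, -5.59 at 4 days), layna (-4.92, -5.19 and -5.93), upp1 (-4.89 at 3 days), egln3 (-5.09 at 4 days), odc1 (-4.95 at 5 days) and saa (-5.17 at 5 days, adjusted p = 0.0183; 0.101 without fish 1 labelled abnormal and 0.0508 without fish 3 labelled normal). The abnormal-normal differences of any 2 days correlated across the 15430 genes with r = 0.876 (3 and 4 days), 0.885 (3 and 5) and 0.896 (4 and 5), genes not being independent replicates. Genes called in the same direction on 4 and 5 days numbered 2100 higher and 1053 lower, against 494.3 and 139.1 for independent lists, and 1 was called in opposite directions. No liver gene had a difference that changed with the day by limma's moderated F test (0 genes at an adjusted p under the threshold, 290 at an unadjusted p under 0.05; 2 genes passed without fish 1 labelled normal at 3 days).

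Set against the time before transport, livers labelled normal differed in 5659 genes at 3 days (1858 higher, 3801 lower), 6564 at 4 days (2300 and 4264) and 6633 at 5 days (1903 and 4730). Hemopexin, hpxa, fell from 14165 ± 1766.5 TPM to 21.4 ± 7.26 (n = 3), 76.3 ± 71.1 and 88.9 ± 108, and rnasel2 from 937 ± 395 to 12.0 ± 2.55 at 3 days and 12.9 ± 3.72 at 5 days (-6.05 and -5.98). At 4 days the collagen gene col1a1a fell from 217 ± 288 to 1.02 ± 0.480 (-5.90). The mean TPM of fabp10a before transport was 321 ± 172, against the 0s listed above. Rises were led by layna (0.235 ± 0.085 to 85.4 ± 36.5, 79.6 ± 60.6 and 77.7 ± 16.4), tm7sf2 at 3 days (229 ± 56.7, 5.82), upp1 at 4 and 5 days (5.33 and 5.04) and odc1 at 5 days (4.78). Serum amyloid, saa, was listed at 0 in fish 4 before transport and at 2161 to 5260 TPM in the other 3, so its rises of 5.30 at 3 days (adjusted p = 0.0204; 0.122 without that fish) and 5.67 at 4 days (0.0069; 0.103 with only the compared libraries in the fit) rest in part on 1 fish. Medians of all genes were -0.23, -0.22 and -0.30, and median-of-ratios rescaling gave 3380 higher and 3485 lower, 3781 and 3814, and 3668 and 3829. With only the compared libraries in the fit the counts were 2120, 2934 and 3304.

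In spleen the labels differed in blood-cell genes. Averaged over the 3 days (n = 11 per label), the alpha-globin gene hbae5 stood at 75934 ± 37273 TPM in spleens labelled abnormal and 2834 ± 2269 in spleens labelled normal (log2 difference 4.95, SE 0.42, limma adjusted p = 6.76e-11), against 44906 before transport. Erythroid markers were higher in spleens labelled abnormal in 13 of 17 cases and lower in 2 (13 and 2 when adjusted over the list alone; camera adjusted p = 1.66e-17, adjusted p = 0.226 with an estimated correlation). Among these were cahz (459.9 ± 150 against 29.3 ± 22.7, 4.15), hemgn (251 ± 68.6 against 17.7 ± 11.9, 3.88) and the erythropoietin receptor gene epor (105 ± 34 against 9.0 ± 7.99, 3.54). Thrombocyte markers, of the fish cells that act as platelets, were higher in 8 of 11 and lower in 2 (8 and 2 over the list alone, camera adjusted p = 9.04e-10, adjusted p = 0.226 with an estimated correlation). Among these were the thrombopoietin receptor gene mpl (389 ± 142 against 29.3 ± 12.6, 3.65), gp9 (3.13) and gp1bb (2.12). Other large rises were plaat1l (4.26), phospho1 (3.97) and the Rh blood-group gene rhd (125 ± 48.4 against 7.38 ± 5.56, 3.96).

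The largest falls in spleens labelled abnormal included genes of immunity and stress. The interleukin 13 decoy receptor gene il13ra2 stood at 0.411 ± 0.4 TPM against 68.5 ± 42.9 (-5.5), acod1, which makes the antimicrobial metabolite itaconate, at 1.55 ± 2.55 against 70.5 ± 67.4 (-4.85), and steap4 at 8.70 ± 13.6 against 184 ± 97.5 (-5.07). Also lower were tp53i3 (35.8 ± 59.2 against 703 ± 148, -5.28), rrad (-5.00), the protease gene adamts1 (1.49 ± 1.12 against 75.1 ± 26.8, -4.99), igfbp1a (-4.96) and upp1 (54.5 ± 47.8 against 1088.5 ± 281, -4.52). Cell cycle genes were lower in 32 of 33 cases (32 over the list alone, camera adjusted p = 1.84e-05). Among these were kif23 (-2.32), aurka (-2.06) and ccnb3 (-1.94). Hypoxia genes were lower in 20 of 23 with 2 higher (20 and 2 over the list alone; 0.00116), with hif1al (47.7 ± 29.2 against 439 ± 97.3, -3.39) and ldha (94.6 ± 37.2 against 814 ± 436, -2.99). The unfolded protein response was lower in 24 of 26 (24 over the list alone; 0.000308), with hsp90b1 (-2.19), pdia6 (-1.81) and ddit3 (-1.60). Oxidative phosphorylation was lower in 30 of 33 (30 over the list alone; 0.000535), with sdhb (-1.49), atp5f1b (178 ± 42.1 against 506 ± 71.0, -1.52) and ndufa10 (-1.17). With an estimated correlation the adjusted p of each of these 4 lists was 0.789. Neutrophil markers were lower in 7 of 7 cases (camera adjusted p = 0.0698), macrophage markers in 11 of 13 with 1 higher (0.0968), interferon genes in 8 of 21 with 1 higher (0.204) and growth axis genes in 7 of 14 with 4 higher (0.431), and these 4 lists did not pass. Hepatocyte markers summed to 3120 ± 974 (n = 3), 4239 ± 980 and 5148 ± 1580 TPM in spleens labelled normal at 3, 4 and 5 days and 594 ± 216 (n = 3), 1980 ± 2388 and 1027 ± 791 in spleens labelled abnormal, but 0 of 22 rose and 3 fell, and the list did not pass (camera adjusted p = 0.0769).

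**Figure D4:**
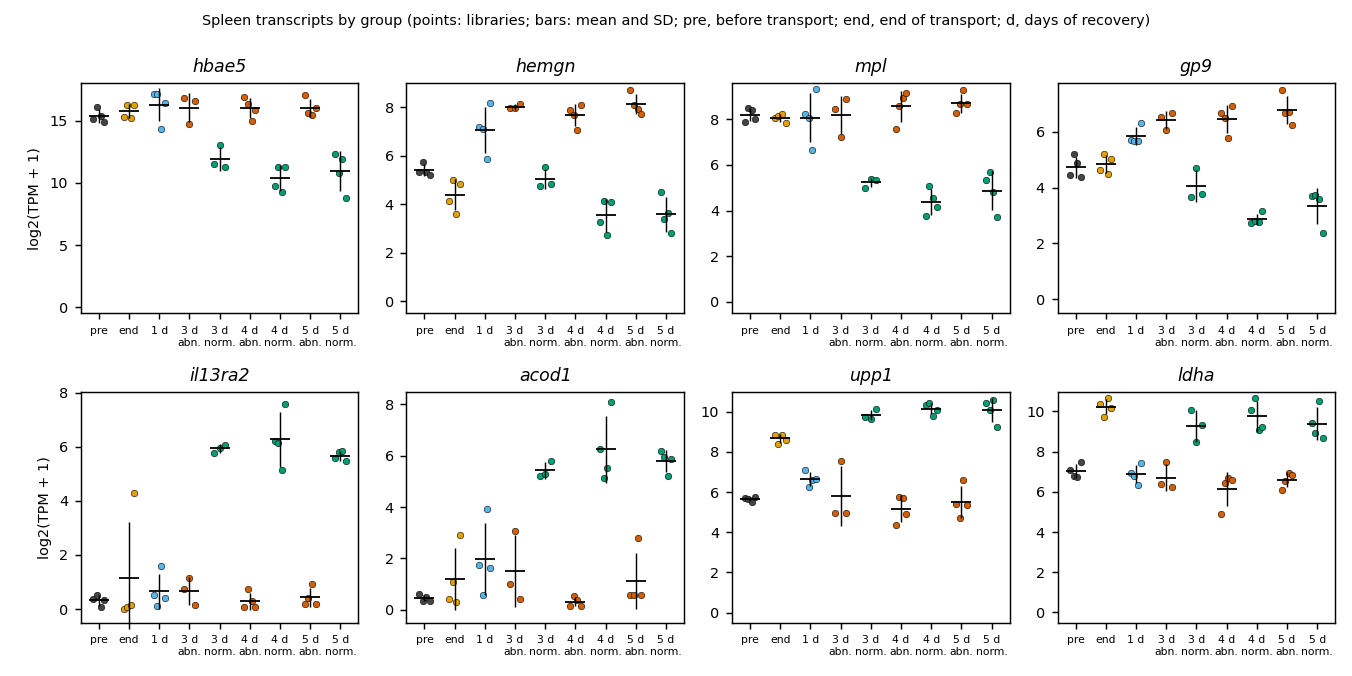
Log2(TPM + 1) of 8 genes in the 34 spleens by group; points are libraries, bars the group mean and SD, and fish at 3, 4 and 5 days carry the label abnormal (abn.) or normal (norm.). The red-cell and thrombocyte genes hbae5, hemgn, mpl and gp9 are lower, and il13ra2, acod1, upp1 and ldha higher, in spleens labelled normal.

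8 other lists passed camera in spleen between the labels. Lower in fish labelled abnormal were the proteasome (27 of 29, 27 over the list alone, camera adjusted p = 0.00213), ribosome biogenesis (27 of 29, 28 over the list alone; 0.00934), the glucocorticoid response (15 of 19, 15 and 1 higher over the list alone; 0.00969), pro-inflammatory genes (21 of 25, 22 and 1 higher over the list alone; 0.0108) and glycolysis (12 of 16 with 1 higher, 12 and 1 over the list alone; 0.0326). For 3 lists camera gave a rise although most members that moved fell, because all genes had a median of -0.51: B cell markers (4 rose and 5 fell of 14, 4 and 5 over the list alone; median -0.24, mean 0.08; 0.0326), T cell markers (4 rose and 8 fell of 16, 4 and 8 over the list alone; median -0.49, mean -0.04; 0.0483) and cytosolic ribosomal proteins (6 fell of 63, 3 over the list alone; median -0.29, mean -0.27; 0.0492). Adjusted p with an estimated correlation was 0.858 for ribosomal proteins and 0.789 for the other 7. After median-of-ratios rescaling the proteasome (0.0881), B cell (0.0686) and T cell (0.0881) lists did not pass, while macrophage markers (0.0243) and the clock (0.048, 0.0698 as deposited) did. With a pseudocount of 0.1 ribosomal proteins did not (0.0579). Of the infection markers, saa stood at 135 ± 216 and 153 ± 232 TPM (-1.16, adjusted p = 0.268) and the interleukin gene il1b at 1.26 ± 0.529 and 2.04 ± 1.14 (-0.38, adjusted p = 0.0501; 0.0479 with a pseudocount of 0.1).

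**Figure D5:**
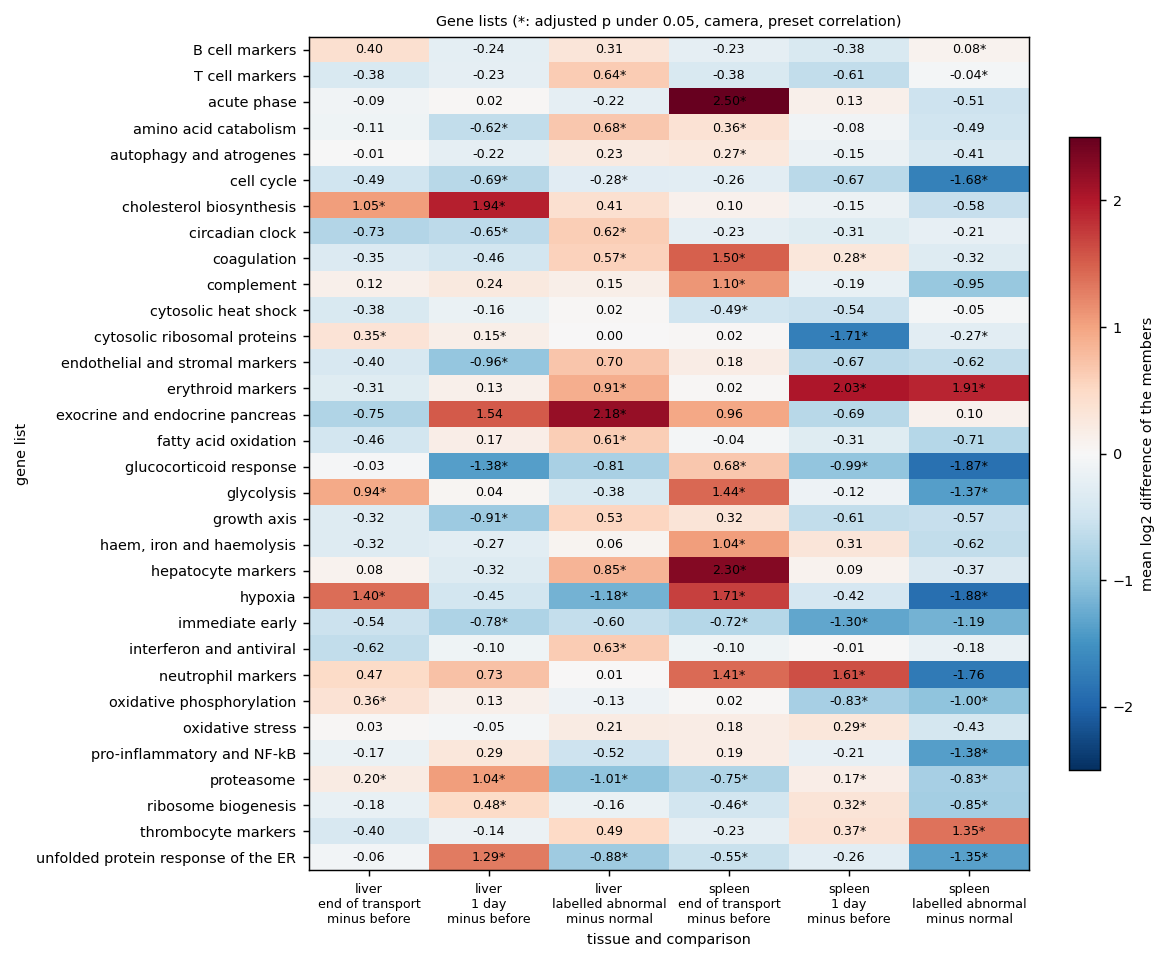
Mean log2 difference of the members of each gene list that passed camera in at least 1 of 6 comparisons, by tissue and comparison; colour and number give the mean, and a star marks an adjusted p under 0.05 with the preset correlation, none of which holds with an estimated correlation. Hypoxia means are 1.40 and 1.71 at the end of transport in liver and spleen and -1.18 and -1.88 between the labels.

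The spleen count over the 3 days was 11140 of 17998 genes, 1394 higher and 9746 lower in fish labelled abnormal, and this split followed the scaling. Median-of-ratios rescaling gave 4992 higher and 5115 lower, and without the 10 most abundant genes 3665 were higher and 5369 lower. Those 10 genes took 38.8 ± 7.5% (n = 3), 37.6 ± 17.8% and 32.3 ± 11.8% of the TPM in spleens labelled abnormal at 3, 4 and 5 days and 9.8 ± 1.4% (n = 3), 6.2 ± 1.0% and 6.5 ± 2.2% in spleens labelled normal. By day 6028 (373 higher, 5655 lower), 7577 (854 and 6723) and 5614 (924 and 4690) genes were called, with medians of -0.62, -0.55 and -0.37, against 1747 and 2132, 3418 and 3496, and 3209 and 3417 after median-of-ratios rescaling. Other settings that moved them are given below.

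Day by day, hbae5 was among the largest rises in spleens labelled abnormal (4.11, 5.64 and 5.09), with plaat1l (4.45) and phospho1 (3.33) at 3 days, rhd (4.72) and cahz (4.58) at 4 days, and cahz (4.85) and hdr (4.78) at 5 days. The fall of il13ra2 was among the 3 largest on every day (-5.26, -5.98 and -5.25), with adamts1 (-5.35) and steap4 (-5.17) at 3 days, acod1 (-5.93) and rrad (-5.92) at 4 days, and tp53i3 (-5.40) and igfbp1a (-5.31) at 5 days. Across the 17998 genes the differences of 2 days correlated with r = 0.837 (3 and 4 days), 0.834 (3 and 5) and 0.875 (4 and 5), and 686 genes were called higher and 4332 lower on both 4 and 5 days, against 43.8 and 1752 for independent lists. By the moderated F test 3 spleen genes had a difference that changed with the day (254 at an unadjusted p under 0.05), and 209 with array weights. The 3 are the unnamed loci LOC119912705 (adjusted p = 2.41e-07), LOC119912706 (0.000443) and LOC119908745 (0.0315), named here after their values were seen.

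Spleens labelled normal differed from those before transport in 3676 genes at 3 days (2480 higher, 1196 lower), 4005 at 4 days (2508 and 1497) and 3677 at 5 days (2353 and 1324). Rises were led by steap4 (1.28 ± 0.802 to 217 ± 64.0 (n = 3), 174 ± 117 and 168 ± 117 TPM), il13ra2 (0.255 ± 0.162 to 60.7 ± 6.44 (n = 3), 92.5 ± 69.3 and 50.5 ± 6.46), mmp9 at 3 days (412 ± 269, n = 3, 5.45) and acod1 at 4 and 5 days (5.80 and 5.35). Falls included the smooth-muscle actin gene acta2 (532 ± 137 to 29.1 ± 16.8 (n = 3) at 3 days and 26.1 ± 16.2 at 4 days), nanos1 (69.4 ± 36.9 to 2.95 ± 1.57 (n = 3), 2.51 ± 2.08 and 2.82 ± 2.04), mst1rb at 3 days (-4.24), hbae5 at 4 and 5 days (-4.99 and -4.44) and col1a1a at 5 days (233 ± 46.0 to 16.9 ± 6.63). The medians of all genes were 0.25, 0.16 and 0.18, and median-of-ratios rescaling gave 2503 higher and 2636 lower, 2791 and 3163, and 2626 and 2855. Settings that moved these counts are given below. At 3 days 2421 and 2143 genes were called without fish 2 or fish 3 labelled normal.

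Whether liver and spleen changed differently was tested in 1 fit of all 68 libraries. At the end of transport 1210 of 18666 genes differed in their change, 384 with a higher and 826 with a lower difference in liver. Among the named genes the change was larger in liver for epoa (3.12 against -0.70, adjusted p = 0.0016) and tm7sf2 (3.71 against -0.40, 0.000182) and larger in spleen for tpi1b (0.61 against 2.57, 0.00534), hpxa (-0.12 against 4.36, 0.00103) and rrad (-0.07 against -4.13, 0.000244). For egln3 (0.696), egln2 (0.89), ldha (0.629), upp1 (0.314), znf395a (0.464) and ciarta (0.863) no difference was detected. A 1.95% share of liver RNA would give 103.1% of the rise of hpxa in spleen. Without the 487 genes far higher in liver 961 genes differed, 350 with a higher and 611 with a lower difference in liver. Median-of-ratios rescaling gave 2415 genes (1248 higher, 1167 lower), quantile normalization 2613 and array weights 3667. Of 14762 genes tested in both tissues 117 rose and 174 fell in both, against 22.3 and 91.6 for independent lists, and 37 were called in opposite directions, a number not set against independent lists. Across these genes the changes of the 2 tissues correlated with r = 0.275.

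Between the labels 10110 of 18666 genes differed by tissue, 8851 with a higher and 1259 with a lower difference in liver, or 5229 and 3955 after median-of-ratios rescaling. Such genes were fabp10a, hpxa (7.54 in liver against 0.04 in spleen, adjusted p = 1.41e-16), rnasel2 (6.30 against 0.45, 1.28e-16), layna (-5.34 against -0.29, 5.97e-15), il13ra2 (-0.05 against -5.50, 2.77e-17), epoa (-2.99 against 0.13, 4.98e-07) and slc41a1 (-4.48 against 1.45, 2.08e-15). Not shown to differ were upp1 (-4.85 against -4.52, 0.593), egln2 (-3.14 against -2.83, 0.556), ddit4 (-3.56 against -4.02, 0.566), nfil3-2 (-1.75 against -1.74, 0.987) and odc1 (-4.73 against -3.77, 0.0716). In both tissues 560 genes were higher and 2634 lower in fish labelled abnormal, against 247.8 and 1784 for independent lists, and 1538 were called in opposite directions. That last number was not set against independent lists or recounted after rescaling. Across the 14762 genes tested in both tissues the 2 label differences correlated with r = 0.399.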

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

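The 3 patterns weighed here were chosen after the results were seen. The tests of exchanged labels, of abundant genes and of red cells were also written after the values they measure had been seen, and those of liver RNA before, except where genes are said to be singled out.

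The stress genes ddit4 and creld2 and the acute-phase gene saa were higher in livers labelled normal than in those labelled abnormal, as were the proteasome, hypoxia and unfolded protein response lists, whose calls are lost with an estimated correlation (adjusted p = 0.867 for each). The acute phase, glucocorticoid and heat shock lists did not pass, and hpxa was far higher in livers labelled abnormal. Labels exchanged on some days only can be excluded, since the label difference correlated between any 2 days with r of at least 0.834. Labels exchanged on all days cannot be told from a real state of these fish. All 11 of 11 livers labelled abnormal lay nearer to the mean liver before transport than the nearest labelled normal, as did 8 of 11 spleens to the mean spleen. Root mean square log2 distances were 0.722 ± 0.051 (highest 0.828) in livers labelled abnormal and 1.169 ± 0.049 (lowest 1.071) in livers labelled normal (n = 11 each). In spleen they were 0.906 ± 0.234 (highest 1.486) and 0.987 ± 0.041 (lowest 0.926). A few abundant genes taking up the TPM can be excluded. The 10 most abundant took 24.8 ± 2.9% of it in livers labelled abnormal and 26.1 ± 2.5% in livers labelled normal (n = 11 each), which shifts every other gene by 0.025 (SE 0.022) log2, against list medians of -1.05, -1.16 and -0.81. The labels give no definition of either word, so no biological explanation was tested.

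In spleens labelled abnormal most changed genes were lower. The 10 most abundant genes took 36.0 ± 12.6% of the TPM in these and 7.3 ± 2.2% in spleens labelled normal (n = 11 each), which shifts every other gene by -0.564 (SE 0.095) log2, beside a median of all genes of -0.513. TPM are relative, so this larger share and a real fall of most genes cannot be told apart. The mean of the thrombocyte list lay 2.63 (SE 0.55) log2 above that of the macrophage list. This argues against red cells diluting all other transcripts alike as the whole cause. The SE is over the 11 and 13 list members, not over fish. A share of red cells and thrombocytes rising together was not tested. No other biological explanation was tested.

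Hepatocyte transcripts were higher in spleens at the end of transport. Liver RNA carried into the samples fits: 50 of 50 liver-restricted genes were higher, their implied liver share had a median of 1.95% with an interquartile range of 0.73 on the log2 scale, and by spleen it was 0.985, 3.08, 0.41 and 3.43%. Carried-in liver RNA can be excluded as the whole of the hypoxia and glycolysis rise, where it gives 0.93% of the rise of the median gene. Of those 22 genes it gives much of the rise of gapdh (96.5%), pklr (127.5%) and igfbp1a (36.7%), and outside them 103.1% of that of hpxa, all singled out after their values were seen. All 50 liver-restricted genes were also higher in the mean spleen labelled normal than before transport (median share 0.587%). Only 14 were higher in it than in the mean spleen labelled abnormal. The share against before transport gives at most 2.0% (igfbp1a) of the label difference of the 19 named genes lower in spleens labelled abnormal, a test added afterwards. Release of liver transcripts into the blood of the spleen could look the same and was not tested.

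Chance puts a library far from the other 3 of its group in 5% of groups, and 19 of 168 library measures had such a library. Before transport these were liver 4 in its correlation with the group (0.880 against 0.954 to 0.966) and its principal component 3 (23.6 against 17.8 to 18.3), spleen 1 in correlation (0.967 against 0.960 at most), spleen 2 in summed erythroid markers (966 against 553 to 614 TPM) and spleen 3 in small nuclear and nucleolar RNA (912 against 276 to 339 TPM). After 1 day they were spleen 4 in erythroid markers (11797 against 2233 to 2825 TPM) and spleen 3 in rps3a (274347 against 954 to 2060 TPM).

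Among fish labelled normal these were liver 4 at 4 days in erythroid markers (82.8 against 45.8 to 49.3 TPM) and small nuclear and nucleolar RNA (213 against 57.6 to 81.9 TPM), and at 5 days spleen 1 in the TPM of its 10 highest genes (11.5 against 7.64 to 8.10%) and principal component 3 (-19.4 against -10.3 to -8.55) and spleen 3 in correlation (0.957 against 0.963 to 0.964). Among fish labelled abnormal at 5 days these were liver 1 in genes at 1 TPM (13895 against 12297 to 12553), principal component 2 (28.2 against -29.4 to -24.2) and hepatocyte markers (139111 against 193865 to 195168 TPM), spleen 1 in genes at 1 TPM (14960.0 against 16094 to 16326), its 10 highest genes (50.5 against 24.7 to 29.1%) and erythroid markers (3340.1 against 1568 to 1779 TPM), and spleen 3 in pancreas markers (1175 against 15.0 to 109 TPM).

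A library lay outside its group of 4 in 37 of 588 named gene and group pairs in liver (6.3%) and 34 of 679 in spleen (5.0%), against the 5% of chance, and liver 1 labelled abnormal at 5 days did so in 9 named genes. Tests of the difference called 1210 genes between tissues at the end of transport, 10110 for the label difference and 3 spleen genes by day.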

How the results depend on the processing

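Of 269 named gene-comparisons none turned direction under any setting. Calls stayed the same in all 269 with quantile normalization, robust empirical Bayes and the replicate block, in 257 of 257 with a filter of 5 TPM, in 263 of 263 without the 10 most abundant genes and in 23 of 23 without genes far higher in liver. 1 call was gained with either pseudocount, no filter or median-of-ratios rescaling, and 3 with array weights. Only the compared groups' libraries lost 35 and gained 1, taking out libraries that stand apart lost 13 of 191, and leaving out 1 library lost 24 and gained 11 of 3012. Unless its construction (fewer genes, a stricter threshold) shows it, the cause was not tested.

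Counts of changed genes that moved by over 1.5 times follow. With TPM of at least 5 in 3 libraries they were 989 for liver at the end of transport and 4393 for normal livers at 5 days. With only the compared groups' libraries they were, in liver, 139 at the end of transport, 194 after 1 day and 2120, 2934 and 3304 for normal fish at 3, 4 and 5 days, and in spleen 6177, 504, 7746, 7430 and 6953. With a log2 difference of at least 1 they were 1012 for liver at the end of transport, 2440 after 1 day, 4036 and 4057 for normal livers at 4 and 5 days, 2572 and 2842 for abnormal against normal livers at 4 and 5 days, 2719 for their mean, 4690 for the mean in spleen and 5662 for its difference between tissues. Without the libraries that stand apart liver had 1123 at the end of transport and 2091 after 1 day.

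Scaling moved these: median-of-ratios rescaling gave 4169 for abnormal against normal livers at 3 days, and in spleen 4709 at the end of transport, 6182 after 1 day and 3879 for abnormal against normal at 3 days, with 2415 for the tissue difference at the end of transport. Quantile normalization gave 4200, 4832, 6166, 3911 and 2613 for the same 5, and 5523 for normal spleens at 5 days. Without the 10 most abundant genes spleen had 3506 at the end of transport and 3271 for abnormal against normal at 3 days. Array weights gave 6852, 7811 and 7938 for abnormal against normal livers at 3, 4 and 5 days, and in spleen 7405 at the end of transport, 8946 after 1 day, 9426, 8608 and 8298 for normal fish at 3, 4 and 5 days, 12717 and 8744 for abnormal against normal at 3 and 5 days, 209 for the change with the day, and 3667 for the tissue difference at the end of transport.

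Leaving out each library in turn gave 830 to 3588 genes in liver at the end of transport, 1941 to 5004 after 1 day, 1390 to 2963 for abnormal against normal at 3 days and 0 to 2 for the change with the day. In spleen it gave 1422 to 1810 at the end of transport, 1838 to 6454 after 1 day and 2143 to 3178 for normal fish at 3 days.

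The means of 3 days against before transport, added later, moved too. For livers labelled abnormal the count was 862 with the filter of 5 TPM, 2422 with median of ratios, 2695 with quantiles, 454 with only the compared groups' libraries, 2323 with array weights, 610 with a log2 difference of at least 1, 719 without the libraries that stand apart and 662 to 2842 without 1 library. For livers labelled normal it was 5175 with the filter and 4103 with the log2 difference. In spleen it was, for fish labelled abnormal, 8837 with array weights, 2607 with the log2 difference and 3289 to 5828 without 1 library, and for fish labelled normal 9389 with only the compared groups' libraries, 10427 with array weights and 2930 with the log2 difference.

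With an estimated inter-gene correlation 0 gene lists passed in any comparison, and with median-of-ratios rescaling 7 of the 13 lists of the label difference in liver did. Among genes of at least 5 TPM the label differences in liver correlated between days with r = 0.899, 0.908 and 0.918.

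Within a tissue the numbers of the fish do not pair the samples: deviations of same-numbered libraries correlated with a mean r of -0.01 in liver (17 of 129 pairs over 0.1) and 0.009 in spleen (26 of 129). Between liver and spleen of 1 condition it was 0.134 for the same number (23 of 34 pairs over 0.1) and -0.047 for different numbers, so whether both organs come from 1 fish is left open. The replicate block gave 1730 genes for liver and 2482 for spleen at the end of transport, 7649 and 11329 for the mean label difference, and, as a random block, 1340 and 10273 for the tissue differences, so no count moved by over 1.5 times. Count tools were not run, and TPM give no depth limits.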

Other observations

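In this part the tests chosen only after values were seen are the comparisons of the means of 3 days with fish before transport and the fit without the library that stands apart. The following genes, all members of lists written in advance, were singled out after their values were seen. Of 14 B cell genes in spleen 4 were higher in spleens labelled abnormal than normal, namely cd79a of the B cell receptor (2.21), the lineage factors ebf1a (2.04) and pax5 (1.76), and the kinase gene blk (1.58). Lower were prdm1a (-1.83), prdm1c (-1.24), bcl6ab (-1.48), bcl6b (-0.94) and blnk (-0.67), and no test asked whether these go with stages of the B cell. Glucocorticoid targets were lower in the same spleens: fkbp5 (-3.68), klf9 (-3.78) and dusp1 (-3.89), so these were higher in spleens labelled normal, and fkbp5 was higher in livers labelled normal too (-3.16).

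In the acute phase list of liver the hemopexin-like genes moved in opposite directions, hpxa by 7.54 and hpxb by -3.79 in livers labelled abnormal against normal. Higher like hpxa were fetub (2.22) and itih2 (2.19), and lower like hpxb were saa (-3.98), leap2 (-2.62), tfa (-1.39), fga (-1.19) and fgb (-0.93). The urea cycle gene cps1 was lower in livers labelled abnormal (-2.79). At the end of transport clock genes fell in liver, among them nr1d1 (-2.0), per3 (-2.26), per1b (-1.96) and dbpb (-2.32), and since both times were sampled hours apart, a daily rhythm without transport could give such a change, which the 1886 genes called at that time (1123 without the library that stands apart) do not separate.

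Fish labelled abnormal were set against fish before transport in comparisons added after the data were seen. For the mean of 3 days livers labelled abnormal differed in 1432 genes (405 higher, 1027 lower) and livers labelled normal in 7964 (2609 and 5355). The first count rests on single fish before transport: without fish 1, 2, 3 or 4 it was 2842, 2831, 877 or 662, the last with 420 higher and 242 lower. Median-of-ratios rescaling gave 1084 higher and 1338 lower for it, array weights 1781 and 542, and rescaling gave 4332 and 4420 for livers labelled normal. In spleen the counts were 5154 for fish labelled abnormal (613 and 4541) and 5779 for fish labelled normal (3878 and 1901), with medians of all genes of -0.352 and 0.196. After median-of-ratios rescaling the splits were 2622 and 3394, and 3600 and 3714, so these splits follow the scaling. Without spleen 4 before transport the first was 3289.

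Regrouping the compared libraries in other ways asks whether chance can be excluded for a count. For liver at the end of transport it cannot: 5 of 35 splits called at least as many genes as the real one (1886), the highest 4980, which points to structure among the libraries. After 1 day in spleen it cannot either, with 3 of 35 splits and a highest of 4749 against 3609. The real split called the most genes for liver after 1 day (1 of 35 splits, the real one with 4218, highest other 2121), normal livers at 3, 4 and 5 days (5659, 6564 and 6633 against 5391, 2207 and 3157), spleen at the end of transport (2197 against 84) and normal spleens (3676, 4005 and 3677 against 1261, 1 and 6). A rank of 1 of 35 is the lowest that these splits allow. Ranks were not corrected for the number of counts, so they argue against chance without excluding it.

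Between the labels the real split also called the most genes at 4 and 5 days in liver (4028 and 4447 against 1 and 286) and spleen (7577 and 5614 against 2136 and 6), and for the mean of 3 days (7772 against 3544 in liver and 11140 against 4107 in spleen, 1 of 100 splits each). At 3 days 10 splits are too few to tell (2731 against 2 in liver and 6028 against 1 in spleen). The change with the day was called in 0 liver genes, and all 100 splits reached that, up to 1660. In spleen 3 of 100 splits reached the 3 genes, but the highest called 4070, which points to structure among the libraries. For tissue differences 2 of 100 splits reached the real count at the end of transport (1210 against 1465) and 1 of 100 between the labels (10110 against 3636).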
